A study of Mus musculus with 6 samples.

How the data were processed

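RNA from mouse heart was measured on 6 one-colour Agilent arrays, 3 from mice that had a sham operation and 3 from mice whose left anterior descending coronary artery had been tied off to cause a myocardial infarction (MI). Per the labels, the mice were males aged 10 weeks, and total RNA was treated with RNase R, an exonuclease that degrades linear RNA and spares most circular RNA (circRNA), before it was copied with random primers and labelled with Cy3. The labels disagree with each other on 2 points. The treatment protocol and the series' design text place the tissue 1 day after ligation, while the source name of the MI samples speaks of 4 weeks. The design text describes an array of mRNAs and long noncoding RNAs, while the labelling protocol describes circular RNA, and the probe names in the files are those of a circRNA array. The time after ligation is therefore left open throughout.

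Each array file holds the scanner output of 15712 spots. The authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 11.0.1.1, per the file headers, which subtracts the background and detrends within the array and leaves the intensity unscaled between arrays. The files also give the raw intensity of each spot and of its local background, and flags for spots well above background and for outliers. The deposited value table of the series holds log2 values for 14225 probes, and limma is named without a version or a role in the submitters' processing notes. Its 6 columns had medians of 5.72, 5.70 and 5.71 in sham and 5.68, 5.68 and 5.69 in MI and a common maximum of 17.07 on the log2 scale, so the columns share nearly one distribution. In each column the values ranked probes as the raw spot intensity of that array did, with rank correlations of 0.995 to 0.999 across probes. The scale, log2 intensity, was inferred, and the rank correlations cannot show it, since they are the same on any rising scale. The background handling and the normalization behind the table are not given in the sources used here.

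The array carries 14236 circRNA probes with 1 spot each and 50 mRNA probes with 10 spots each. The files give circRNA probes an identifier and no gene, position or class, so they are counted as a group and only 2 identifiers per direction are printed. The array design was built on mm9, and no coordinate is printed. The accession of an mRNA probe was looked up, without versions, in a RefSeq gene table of the assembly GRCm38.p6, used for names alone. It named 44 of the 50 mRNA probes and left 6 under their probe name. Control probes and unnamed custom probes were kept out of the main test and were put through the same scaling and test on their own.

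The main values were log2 of the processed intensity of each probe minus the 75th percentile of the array's own log2 probe values. The percentile was taken over all probes that the scanner output does not mark as controls. These include the probes named circRNA control, CUST and MM9NEGATIVE. Spots flagged as outliers within their own pixels or against their replicate spots counted as missing, and the spots of one probe were averaged on the log2 scale. A probe was tested where it was well above background on at least 3 of the 6 arrays, whichever group they belonged to. A probe with 10 spots counted as above where over 50% of its unflagged spots were. MI was compared with sham by lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. All adjusted p-values are from this moderated test unless another is named. A positive log2 fold change means higher in MI. Values per group are means ± SD of 3 arrays, and fold changes carry the standard error (SE) of the fit. For a probe that was not well above background on any array of a group, the ratio is given as a lower bound, the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own value and the lowest value well above background on that array. Differences in single values per array were tested with an exact permutation test, two-sided, for which 0.1 is the smallest p that 3 arrays against 3 can give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

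The test was tried on simulated arrays with the means and moderated variances of the 11554 tested probes, of which 200 were changed by a known amount in each of 10 runs. It called 0.299% of the probes changed 1.5-fold, 3.43% of those changed 2-fold and 78.3% of those changed 4-fold, with the right sign, and 6.55% of its calls were unchanged probes. The simulated arrays had independent errors and few changed probes. With only 200 changed probes the adjustment is stricter than in the real comparison.

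Before the data were examined, the grouping, the test, 17 gene lists, the alternatives and the rule for named genes were fixed. The rule takes the 12 largest changes per direction among probes past the threshold whose 3 MI values all lie on one side of the 3 sham values, and up to 3 probes per gene list with the smallest p. Further parts take probes of a few set genes, none of which is on a named mRNA probe, and the probes with the largest bounds, whose highest values are given. Since circRNA probes carry no gene name, the first part was applied to the mRNA probes on their own, a step taken after the files were seen. The printed circRNA identifiers are the 2 per direction with the largest fitted changes under the same conditions. Hspb7 was added after its values were seen. The value of 1 gene that the rule names is not reported here. No gene list had 5 or more measured genes, so none of the 17 was tested. No comparison of circRNA classes was made, for want of a class for any probe.

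The alternatives were quantile normalization, normexp background correction with an offset of 50, centring on the median, another base for the percentile, no filter on detection or detection on all 6 arrays, the authors' deposited log2 values, a variance trend with robust estimation, array weights, keeping flagged spots, the slide or the replicate number as a block, leaving out each array in turn, other thresholds and a plain two-sample test. The files have no mean spot intensity column, so normexp used the median spot intensity. Values without any scaling between arrays, and slide 1 on its own with quantile normalization, were added after seeing the data. The scan identifiers put 5 arrays in one scan and the second sham array, Sham 2, in another. No slide label was used, so slide 1 stands for the 5 arrays that share a scan identifier. Whether Sham 2 was on another slide is not known. The number of arrays limits the precision of every value, and the intensities give no count of molecules. The spike-in slope recorded per the file headers was 0 on every array, so no spike-in scale was used.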

Results

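The series asks which RNAs of the mouse heart, mainly circular RNAs, differ in abundance between sham-operated mice and mice with an infarct caused by tying off the left anterior descending coronary artery. It has 3 sham and 3 MI hearts, 1 array each. A circRNA is a closed loop formed when a splice donor joins an upstream splice acceptor, and it survives the RNase R treatment that removes most linear RNA. The 50 mRNA probes on the same arrays were therefore read in RNA depleted of linear transcripts, and their values are probe signals in that RNA, not levels of mRNA in tissue.

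The 75th percentile of intensity over all probes not marked as controls was 68.0, 124 and 103 on the Sham 1, Sham 2 and Sham 3 arrays and 108.5, 153 and 129 on the MI 1, MI 2 and MI 3 arrays. Of the 14236 circRNA probes, 8684 were well above background on all 6 arrays and 1398 on none. The number well above background was 10891 ± 340 in sham and 11165 ± 1249 in MI (SD, n = 3), a difference of 274 that was smaller than the spread between MI arrays (exact permutation test, p = 0.8). It was 994 without MI 1 (exact permutation test, p = 0.1, the smallest possible), -52.3 without MI 2 and -120 without MI 3, and 105.5 without Sham 1 and 445.5 without Sham 3. The array with the fewest was MI 1, with 9725, against 11817 on MI 2 and 11953 on MI 3. The MI arrays had a wider range of intensity. The 95th percentile was 54.9 ± 3.59 times the median in MI and 28.5 ± 3.02 times in sham (SD, n = 3), with no overlap between groups (exact permutation test, p = 0.1, the smallest possible).

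Circular RNA signals differed widely between infarcted and sham hearts. Of 11513 circRNA probes tested, 5818 passed the threshold, which is 50.5% of them, and they went up and down in nearly equal numbers, 2960 higher and 2858 lower in MI. Among probes past the threshold, 696 were at least 4-fold lower and 104 at least 4-fold higher in MI, while the counts at 2-fold were 2436 lower and 2228 higher, with probes not well above background in a whole group counted by their bound. The balance of fitted 4-fold changes depended on the processing. As fitted, without bounds, the main setting gave 724 lower and 128 higher. Over probes well above background on all 6 arrays the counts were 424 and 77, and on the deposited values 229 and 6. Quantile normalization gave 597 and 148, and median centring 448 and 322. With the percentile taken over probes well above background on all arrays they were 1095 and 47. The counts were 49 lower and 58 higher under normexp correction, and 269 and 681 with no scaling. ASCRP4002880 had a fitted log2 fold change of -4.32 (SE 0.46, adjusted p = 0.00277), and it was well above background on 3 sham arrays and on 1 MI array, so the size rests partly on background-level values. Its fall was smaller, with the call kept, under normexp correction (-1.18) and on the deposited log2 values (-1.75).

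A second probe, ASCRP4002388, fell by 3.65 on the log2 scale (SE 0.67, adjusted p = 0.0044), with MI values from -5.67 to -2.71 and 2 of the 3 MI arrays well above background. It was at -1.21 under normexp correction, at -1.78 on the deposited values and at -2.88 without MI 1. In the other direction ASCRP4001386 rose by 2.89 (SE 0.29, adjusted p = 0.00277) and was well above background on all 6 arrays, with 1.30 under normexp correction and 2.02 on the deposited values. ASCRP4013696 was not well above background on any sham array and was on all 3 MI arrays, where it was at least 2.05-fold higher (adjusted p = 0.0205). The call was lost under normexp correction, at a log2 fold change of 0.31 (adjusted p = 0.399), and on the deposited values, at 1.06 (adjusted p = 0.079). Its 3 MI values ranged from -4.07 to -0.45 on the log2 scale, with MI 1 the highest. The bound rests on MI 1, since the mean of the other 2 MI arrays, -3.93, lies below the sham floor of -3.81, and without MI 1 the fitted log2 fold change was 1.97 in place of 3.13. Over all circRNA probes, 146 were well above background on all 3 MI arrays and on no sham array, and 62 showed the reverse. The 62 sham-only probes had bounds of up to at least 6.18-fold, with a median of 2.50, and all 62 passed the threshold. Of the MI-only probes, 133 had a bound above 1, with a median of 1.51 and the highest at least 4.40-fold, and 108 of them passed. Both sets were picked on these same arrays by a difference between the groups, so their pass counts are no separate support.

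The direction of change went with how bright a circRNA probe was. When the 11326 tested probes with a value on all 6 arrays were ranked by mean level, leaving out 187 with a flagged spot, the median log2 fold change in the brightest decile was 1.09, with 61.7% of the probes past the threshold and higher in MI and 8.38% lower. In decile 4, counted from the dimmest, it was -0.31, with 12.7% higher and 34.4% lower. The medians ran from -0.40 to 1.09 over the deciles, and under quantile normalization from -0.06 to 0.48, so the brightest probes stayed above the dimmest in MI with a smaller gap.

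**Figure D1:**
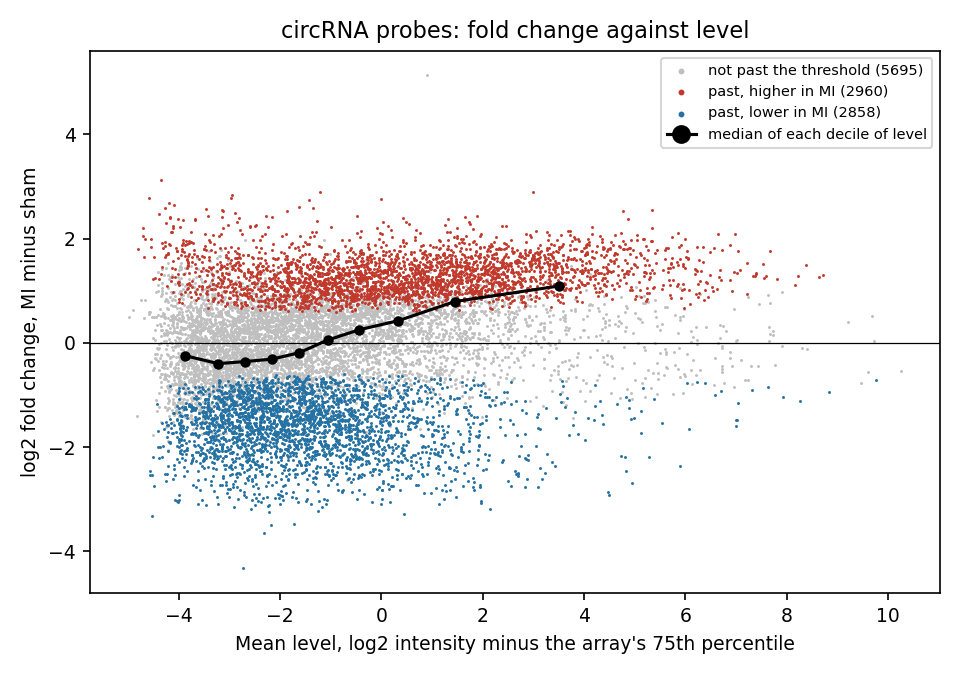
Each point is one of the tested circRNA probes, with its mean level (log2 intensity minus the array's 75th percentile) on the x axis and its log2 fold change, MI minus sham, on the y axis; grey points did not pass the threshold, red points passed and were higher in MI (2960), and blue points passed and were lower (2858). The black line joins the medians of the deciles of level, which reach 1.09 in the brightest.

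The 3 MI and 3 sham values did not overlap for 61.1% of the tested circRNA probes, where chance gives 10%, and 6670 had an unadjusted p under 0.05. The median fold change of all tested circRNA probes was 0.10 on the log2 scale (quartiles -0.93 and 0.90), beside a median SE of 0.30. The balance between higher and lower probes depended on the scaling, with 50.9% of the calls higher under the main scaling, 37.6% when the percentile was taken over probes well above background on all arrays, 60.7% under median centring and 71.3% with no scaling. These settings moved the median fold change of all circRNA probes from 0.10 to -0.16, 0.32 and 0.53 in the same order.

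Arrays within a group were alike, with 1 exception. Over circRNA probes, the correlation across probes was 0.976 between Sham 1 and Sham 3 and 0.976 to 0.983 among MI arrays, and it was 0.823 to 0.872 between these 2 sham arrays and MI. Sham 2, the only array with its scan identifier, had 0.908 and 0.905 with the other sham arrays and 0.875 to 0.906 with the MI arrays. With the slide as a block, which here equals leaving Sham 2 out and comparing the 5 arrays of slide 1, 7893 circRNA probes passed, 4199 higher and 3694 lower. They included 5765 of the 5818 probes, all 5765 with the same direction.

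Among mRNA probes, which were read in the same RNA, 41 were tested and 20 passed the threshold, 14 higher and 6 lower in MI. The counts adjusted over the list alone were the same, and the balance depended on the scaling, with 11 higher and 7 lower when the percentile was taken over probes well above background on all arrays, 19 and 4 under median centring, and 15 and 2 with no scaling. The largest change was a fall at the probe of Ppara, a nuclear receptor that drives transcription of fatty acid oxidation genes. It went from 2.12 ± 0.25 in sham to -1.06 ± 0.64 in MI (SD, n = 3), a log2 fold change of -3.19 (SE 0.35, adjusted p = 0.00277), and lay at -3.28 within slide 1. The probe of H2-Q7, a class Ib histocompatibility gene, fell by 2.05 (SE 0.28, adjusted p = 0.00277). The probe of Lhfp, which encodes a membrane protein, fell by 1.49 (SE 0.26, adjusted p = 0.00406).

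Smaller falls were measured at Acaa2, the thiolase that ends the mitochondrial fatty acid oxidation cycle, and at Actb, which encodes cytoplasmic beta-actin. Acaa2 had a log2 fold change of -0.85 (SE 0.25, adjusted p = 0.0246) and Actb one of -0.71 (SE 0.25, adjusted p = 0.0468). The probe of Hspb7, a small heat shock protein of heart muscle, was at 5.99 ± 0.46 in sham and 5.21 ± 0.09 in MI (SD, n = 3). Its log2 fold change of -0.78 did not pass the threshold (adjusted p = 0.0519), and within slide 1 it was -1.05 (adjusted p = 0.00317, with 0.000871 to 0.505 over its 20 alternatives).

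The 14 mRNA probes that rose comprise 12 with a gene symbol and 2 without, and 1 of the 6 that fell has none. Those with a symbol belong to genes of varied function. The highest was Olfr1307, an olfactory receptor gene, at a log2 fold change of 1.97 (SE 0.32, adjusted p = 0.00326), and a second olfactory receptor probe, Olfr166, rose by 1.33 (SE 0.26). Il2, the T cell growth factor gene, rose by 1.67 (SE 0.26, adjusted p = 0.00308), and Mzb1, an endoplasmic reticulum protein of B lineage cells, by 1.56 (SE 0.27). Lhx1, a homeobox factor of development, rose by 1.39 (SE 0.29). Anxa8, a calcium-dependent phospholipid binding protein, rose by 1.41. Gamt, the last enzyme of creatine synthesis, rose by 1.38, and Spats1, a gene linked to spermatogenesis, also by 1.38. Pex11a, which acts in peroxisome division, rose by 1.27. E2f1, a cell cycle transcription factor, rose by 0.96 (adjusted p = 0.0139), and Apoe, the apolipoprotein of lipid transport, by 0.91 (adjusted p = 0.0212).

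**Figure D2:**
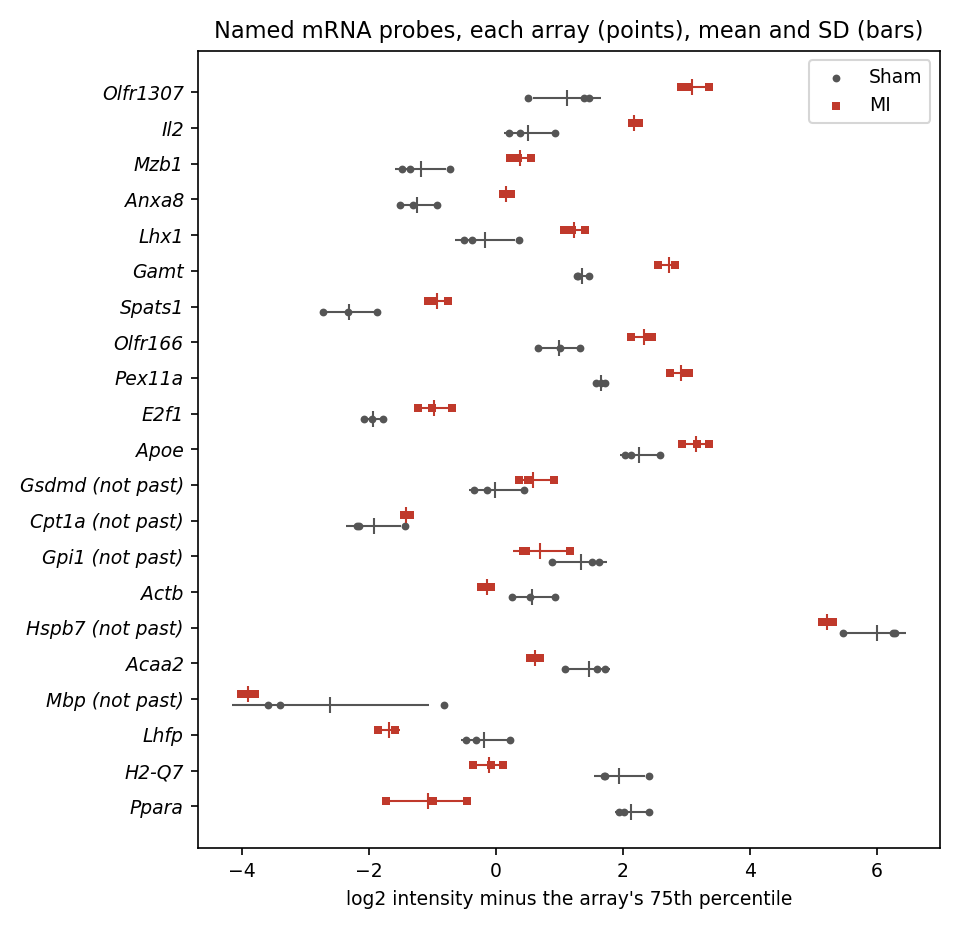
Signal of the named mRNA probes on each array, as log2 intensity minus the array's 75th percentile on the x axis, with grey circles for the 3 sham arrays, red squares for the 3 MI arrays, ticks for the means and bars for the SD. The MI values of Ppara, from -1.73 to -0.46, lie below its sham values, from 1.94 to 2.41, and genes marked as not past did not reach the threshold.

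Few genes of the lists fixed in advance were on these probes. The list of mitochondrial and fatty acid metabolism had 2 tested genes. One was Ppara, above, and the other was Cpt1a, which loads long-chain fatty acids for entry into mitochondria. Cpt1a had a log2 fold change of 0.52 that did not pass (adjusted p = 0.15), while within slide 1 it was 0.76 (adjusted p = 0.00962, with 0.00232 to 0.732 over its alternatives). One gene each stood for 3 other lists, and none of these passed. Mbp, a myelin gene from the list of Schwann cells and neurons, was at -1.30 (adjusted p = 0.147), with Sham 3 at -0.82, the other sham arrays at -3.59 and -3.41 and the MI arrays from -4.00 to -3.80. Without Sham 3 it was at -0.41 (adjusted p = 0.243). Gpi1, a glycolytic enzyme from the hypoxia and glycolysis list, was at -0.65 (adjusted p = 0.121). Gsdmd, which forms the membrane pores of pyroptosis and comes from the cell death list, was at 0.60 (adjusted p = 0.121) and at 0.84 within slide 1 (adjusted p = 0.0184, with 0.0142 to 0.352 over its alternatives). The lists of cardiomyocyte, fibroblast, leukocyte, endothelial and other cell type markers had no tested gene among the named mRNA probes apart from Mbp, so a change in the mix of cells was not measured.

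The calls of Actb, Acaa2, Apoe, E2f1, Spats1, Lhfp and ASCRP4013696 were each lost under at least 1 alternative, with adjusted p of up to 0.616, 0.405, 0.294, 0.177, 0.0562, 0.0657 and 0.399 in that order. Leaving out Sham 1, Sham 3, MI 1, MI 2 or MI 3 ended the call of Acaa2, at -0.73, -0.78, -0.89, -0.85 and -0.81, and of Actb, at -0.73, -0.53, -0.66, -0.74 and -0.73. The call of Apoe ended without Sham 3, MI 1 or MI 3, at 0.85, 0.80 and 0.90, that of E2f1 without MI 1, at 0.82, and that of ASCRP4013696 without Sham 3, at a fitted 3.05. With 3 mice per group, the p-values set each difference against the spread within groups. In the moderated test that spread was estimated from these 6 arrays and drawn toward a value shared by all tested probes.

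Probes that the array design names as controls moved with the group as well, and are set beside the counts above as a measured fact. Of the 14 circRNA control probes, 12 fell in MI, with a median log2 fold change of -1.64, and none rose. Of the 16 DCP probes tested, 10 rose, and of the 8 ETG probes tested, 7 rose, with medians of 0.74 and 1.19. The direction of these 3 classes was the same under quantile normalization, median centring and no scaling. The raw intensity of the negative control spots was 22.0 ± 3.04 in sham and 23.2 ± 0.76 in MI (SD, n = 3; exact permutation test, p = 0.6). Sham 2 had the highest value, 25.5. Within slide 1 every MI array lay above every sham array, with 24, 23 and 22.5 on MI 1, MI 2 and MI 3. Sham 1 and Sham 3 were at 20 and 20.5.

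**Figure D3:**
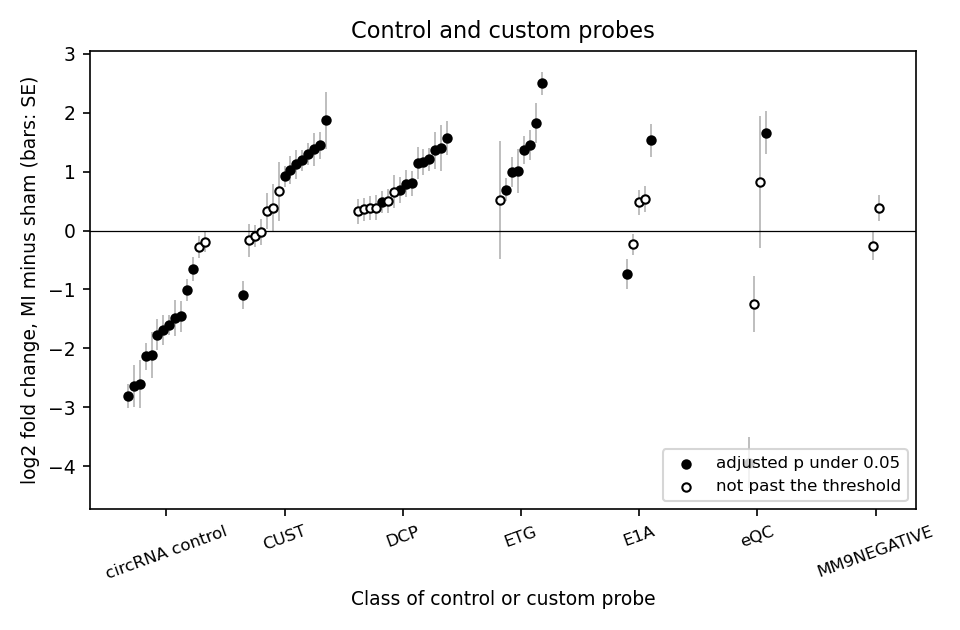
Log2 fold change, MI minus sham, of each tested control or custom probe other than the corner marker on the y axis, grouped by class on the x axis, with bars for the SE; filled points passed the threshold and open points did not. The circRNA control probes lie from -2.81 to -0.19 and the DCP probes from 0.33 to 1.58.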

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

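The tests of control probes and of Sham 2 were chosen only after the results were seen, as were the other splits of the arrays, while quantile normalization and the slide comparison were fixed before the data were examined and used as tests afterwards. The probes in this part lie outside the comparison of circRNA and mRNA probes and were put through the same scaling and test.

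Control and custom probes carried a signal that moved with the group. In MI, 8 of 15 probes named CUST were higher and 1 lower. Of 16 probes of the DCP class tested, 10 were higher, and of 8 tested ETG probes, 7 were higher, with none lower in either class and medians of 0.74 and 1.19 on the log2 scale. Of 5 tested E1A probes, 1 was higher and 1 lower, and of 4 eQC probes, 1 was higher and 1 lower, with eQC-42 at -3.94 (SE 0.43, adjusted p = 0.000409) and eQC-40 at 1.66 (SE 0.36, adjusted p = 0.00536). Of 14 circRNA control probes, 12 were lower in MI and none higher, with a median of -1.64 and a range from -2.81 to -0.19. Under quantile normalization, median centring and no scaling, 15, 14 and 12 DCP probes were higher and 12, 11 and 10 circRNA control probes lower, while the lower E1A call was absent under all 3.

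Several explanations were weighed for the control probes. One shift shared by all probes of an array moves them the same way. It could therefore not be the whole cause of 27 higher and 15 lower probes, which follows from the directions alone. The median of all 65 tested probes of this part was also subtracted from each array. After this 33 of the 42 probes past the threshold passed in the same direction, 18 of the 27 higher and all 15 lower ones. Given the mixed directions, this subtraction is no separate test of a shift as the whole cause. A higher background on the MI arrays is argued against as the whole cause of the 27 higher ones. With 4.11 units, the highest rise of the negative control spots between any sham and MI array, subtracted from every spot of the MI arrays before scaling, 23 of the 27 passed as higher. Intensity distributions that differ between arrays are argued against as the whole cause by quantile normalization, after which 47 probes passed, 38 of them among the 42 and in the same direction. Other causes stay open and were not tested. These include RNA that differs between infarcted and sham hearts and binds these probes. Probe sequences, and the intended targets of the circRNA control and CUST probes, were not used here. A difference between the groups in the RNase R step or in labelling stays open as well. Each of these may also hold for mRNA probes such as Il2 and Olfr1307.

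About 50% of the tested circRNA probes passed the threshold. The real split of the 6 arrays gave 5818 calls and the highest of the 9 other splits gave 0, and for mRNA probes the figures were 20 and 0, so 1 of 10 splits was as large in both. With 10 splits the share cannot fall under 0.1, which is too few to test chance. Under quantile normalization, which gives all arrays one intensity distribution, 5424 circRNA probes passed, 4786 of them among the 5818 and in the same direction, which argues against the wider intensity range of the MI arrays as the whole cause. The comparison within slide 1, where 7893 passed, 5765 of them among the 5818 and in the same direction, argues against the slide. The infarct, the efficiency of the RNase R step in each group and the mix of cells in the tissue were not tested against each other and stay open.

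Sham 2 lay apart from Sham 1 and Sham 3 and partly toward MI. Over the 1252 circRNA probes past the threshold with a fitted change of at least 4-fold within slide 1, its median position between the sham mean (0) and the MI mean (1) on the log2 scale was 0.43 for probes higher in MI and 0.26 for probes lower, and 81.0% of them lay nearer to sham, which argues against a wrong label. RNA of an MI sample mixed into it cannot be told apart from other causes, because over 1196 probes alike in both groups on slide 1 Sham 2 spread 1.72 times as widely as the other sham arrays would give, between the bounds set for either answer. Its own scan, and its slide if that differed, cannot be told apart from the mouse with 1 array in that scan. The difference of Sham 2 from Sham 1 went with that of MI from Sham 3 across probes (correlation 0.48, and 0.46 with the sham arrays exchanged). Hyal3 is an example, chosen after its values were seen, at 0.22 on Sham 2, at -1.59 and -1.75 on Sham 1 and Sham 3, and between 0.10 and 0.32 in MI.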

How the results depend on the processing

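Over the alternatives, between 4163 and 8117 circRNA probes passed the threshold, within 1.5 times the 5818 of the main setting. Leaving out 1 array at a time gave 4163 to 7893, with the highest count without Sham 2, and for mRNA probes 15 to 30. The mRNA count moved by over 1.5 times with array weights, to 33, and on slide 1 alone with quantile normalization, to 32, an alternative chosen after seeing the data, as was no scaling between arrays. Slide 1 alone leaves out Sham 2, and leaving out Sham 2 under the main scaling already gave 30. The cause of the higher count with array weights was not tested. Leaving arrays out changed the difference in probes well above background per array between -120 and 994, and its sign reversed without MI 2 (-52.3) and without MI 3 (-120). No named probe reversed its direction under any alternative that gave it a value. Ppara kept its side of the threshold in all 20 alternatives, with log2 fold changes from -3.49 to -2.23, as did H2-Q7, from -2.44 to -1.58, and Il2, from 1.38 to 2.10. The log2 fold change of Olfr1307 ran from 1.26 to 2.41, that of Mzb1 from 0.86 to 1.99, Anxa8 from 0.78 to 1.85, Lhx1 from 1.03 to 1.83, Gamt from 0.95 to 1.81, Olfr166 from 0.81 to 1.76, Pex11a from 0.77 to 1.71, Spats1 from 0.43 to 1.88, E2f1 from 0.30 to 1.39, Apoe from 0.30 to 1.34, Lhfp from -1.74 to -0.83, Acaa2 from -1.34 to -0.42 and Actb from -0.97 to -0.28. The deposited log2 values gave 4957 circRNA calls, 4490 of them shared with the main setting and in the same direction, and a correlation of 0.908 between fold changes across probes. Nothing in the labels says that equal replicate numbers pair the arrays. The deviations of equally numbered arrays from their group means correlated at -0.09, 0.06 and 0.14. These values cannot exclude a pairing, because Sham 2 lies apart and shapes the deviations of all sham arrays. A replicate block gave 5246 circRNA and 20 mRNA calls. No alternative for gene lists or circRNA classes was run, because neither was tested. Dim probes set the limit of depth, since 1398 circRNA probes were not well above background on any array.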

Other observations

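Other mRNA probes add values that belong to no group above. Prdx2, a peroxide-reducing enzyme, was at a log2 fold change of 0.59 (adjusted p = 0.0693), Hyal3, a hyaluronidase family gene, at 1.28 (adjusted p = 0.0671), and Chgb, a secretory granule protein, at 0.14 (adjusted p = 0.756), and none of the 3 passed the threshold. Alkbh4, a demethylase of the AlkB family, was well above background on no sham array and on all 3 MI arrays. The bound on the ratio of its group means was 1.25-fold, and it did not pass (adjusted p = 0.0749). Its groups overlapped, with MI 1 at -4.24 below Sham 3 at -4.09, so the bound does not show a difference. The probes of Bambi, Cav2, Kcnn2, Gabrg1, Gsta4 and Nup50 were not well above background on any array. These genes were picked after their values were seen.

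Of the 41 tested mRNA probes, Sham 2 lay nearer to the MI mean than to the mean of Sham 1 and Sham 3 on 20 and nearer to the sham mean on 21. On 9 of the 41 it lay on the far side of the other sham arrays from MI, as at Olfr1307, at 0.50 against 1.46 and 1.38. The 4 examples that follow, and Olfr1307, were picked after their values were seen. Taf1a was at 0.53 on Sham 2 and at -1.30 and -1.15 on Sham 1 and Sham 3, Duox1 at 0.18 against -1.49 and -1.23, Carhsp1 at -0.76 against -2.33 and -2.20, and Dnajc11 at -0.58 against -2.49 and -1.98. The MI arrays read -0.16 to 0.32 for Taf1a and -0.28 to 0.33 for Duox1. None of the 4 passed the threshold with Sham 2 in the comparison.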
